A study of Homo sapiens with 8 samples.

How the data were processed

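The series holds 8 libraries of sgRNA sequences amplified from genomic DNA of K562 cells expressing dCas9-KRAB and wild-type or mutant uL16, at day 0 and day 9, with 2 replicates in each of 4 groups. Groups and replicate numbers were taken from the labels. The labels do not say what the mutation is. Per the labels' protocols, transduced cells were selected in puromycin at 1 µg/ml for 3 days, and about 100 PCR reactions with 10 µg of genomic DNA each were made per sample. The labels give the end of the screen as day 9, and the design text as 10 cell doublings.

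The authors deposited a table of raw read counts per sgRNA, with no normalization, 1 column per library. Per the file headers, 4 in number, the reads were trimmed to bases 1 to 39 and counted in the forward direction against a library named as the human CRISPRi version 2 set. The submitters' processing notes name the genome build hg38. The aligner or counting program is not given in the sources used here. The positions in the sgRNA names placed only 2062 of 18761 genes (11%) within 5 kb of the gene in the RefSeq table of GRCh38.p14, so they belong to another build and no coordinates are printed. That table was used for names and chromosomes: 17440 gene symbols of the file matched a current symbol, 1321 an older synonym and 144 neither. Symbols are given as in the sgRNA names.

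Of 209070 sgRNAs listed, 103686 (49.6%) had a count of 0 in all 8 libraries, and 3790 were non-targeting controls. An sgRNA was kept when its mean count over the 8 libraries was at least 20, which left 102987 targeting and 1894 control sgRNAs and removed 500 targeting sgRNAs that had counts. For the main tests the sgRNAs of the primary promoter were summed per gene, and a gene needed at least 3 of them, which gave 95887 sgRNAs and 18905 genes. The sgRNAs of a separate second promoter, present for 1395 genes, were left out of the main tests and tested apart. Of the genes tested, 959 share at least 1 sgRNA with another gene and cannot be told from it by that sgRNA. Library totals ranged from 39233340 to 143585751, the 10 most abundant sgRNAs took at most 0.154% of a library, and control sgRNAs took 1.76 to 1.84%. PCR reads without molecular identifiers are not independent molecules, so depth sets counting error only.

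Counts were analysed in R 4.3.3. Summed counts were normalized by TMM and fitted with edgeR 4.0.16 (quasi-likelihood, glmQLFit and glmQLFTest) with 1 mean per group over all 8 libraries, which leaves 4 residual degrees of freedom and shares 1 estimate of the spread. Contrasts were day 9 against day 0 in each line, the difference of these changes (mutant minus wild-type), and mutant against wild-type at day 9 and at day 0. Adjusted p-values are Benjamini-Hochberg values over genes, with a threshold of 0.05. The same test was run on single sgRNAs. For 28 gene lists, limma 3.58.1 gave camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over lists within a contrast. Fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. The SE of a log2 change was taken from the size of the change and its test statistic.

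The gene lists, the main tests, the alternatives given as planned and the rule for named genes were chosen before the data were examined. The rule took, for each of the 3 main contrasts, up to 10 genes with the largest change each way (5 for the contrasts at day 9 and at day 0) that had an adjusted p under 0.05, at least 75% of sgRNAs with the same sign and replicates that did not overlap. It added 2 members of each list with the smallest p, or up to 4 where a list is described at length, and always ZNF574 and RPL10. Values of LSG1, NMD3, ZNF622 and DNAJC21 outside the difference were added after they were seen, and so were those of the neighbouring gene DNASE1L1.

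The analysis was tested on simulated data drawn from the means and library sizes of these libraries, with 50 genes changed at each of 4 sizes. For the difference between lines, the main test called 38% of 50 genes changed by 0.5 on the log2 scale, 98% at 1, and 100% at 1.5 and 2, and it called 11 of 18705 unchanged genes. All sgRNAs of a simulated gene changed alike, and each sgRNA had the same spread at both days. In these data the sgRNAs of a gene differed and day 9 libraries varied more, so the shares called may be too high for real genes. The alternatives planned were scaling to the control sgRNAs, RLE size factors, DESeq2 1.42.0, no filter or a mean count of at least 100, limma on the mean log2 CPM of sgRNAs (prior count 2), fry over sgRNAs, leaving out the most abundant sgRNA of each gene, a Mann-Whitney test against the control sgRNAs, pooling all promoters, a threshold adding a log2 change over 1, fitting only the libraries compared, replicate blocks, and leaving out each library. Chosen after seeing the data were limma-voom with a weight per day, a robust quasi-likelihood fit, and leaving out genes that share sgRNAs.

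Replicates correlated at 0.954 to 0.974 over genes (log2 CPM) within a group, and their counts differed by more than sampling noise (chi-square per degree of freedom 12.9 to 19.3), so no 2 columns hold the same library. The common coefficient of variation between replicates was 5.77% at day 0 and 9.22% at day 9. The labels do not state that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.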

Results

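Genomic DNA from K562 cells, a human leukemia line, was sequenced to count the sgRNAs of a genome-wide CRISPRi growth screen. In CRISPRi, an sgRNA brings a catalytically inactive Cas9 fused to a KRAB repressor to a promoter and lowers transcription of that gene, so the share of cells carrying an sgRNA falls when the targeted gene is needed for growth. The cells stably expressed either wild-type or mutant uL16, the large-subunit ribosomal protein that RPL10 encodes, and were sampled at day 0 and at day 9 as the labels give it. This made 4 groups of 2 libraries. The design text places the end of the screen after 10 cell doublings and gives its aim as finding factors for the quality control of defective large subunits. Total counts per library were 73728319 and 65249002 (wild-type, day 0), 47353508 and 49703784 (wild-type, day 9), 75971255 and 143585751 (mutant, day 0) and 39233340 and 102693061 (mutant, day 9). The median count per kept sgRNA ranged from 328 to 1219 over the 8 libraries. After filtering, 95887 sgRNAs of 18905 genes were tested, of which 17864 genes had exactly 5 sgRNAs. Log2 changes below are fitted values of the counts summed per gene, each with its standard error (SE), from 2 libraries per group.

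The non-targeting control sgRNAs gave the background of the assay. Over 1894 control sgRNAs, the median log2 change from day 0 to day 9 was 0.04 (SD 0.37 over sgRNAs) in wild-type and 0.03 (SD 0.35) in mutant cells. The median difference between these changes was 0.00 (SD 0.46). When the control sgRNAs were drawn into 378 sets of 5 and tested as genes with edgeR, 2 sets passed the threshold in wild-type cells, 1 in mutant cells and 0 in the difference. At an unadjusted p under 0.05, 35, 18 and 21 sets passed in these 3 tests, where chance gives 19. The 35 in wild-type cells lies above that number, so p-values of the wild-type change may be too small and its calls too many.

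In cells expressing wild-type uL16, the 10 largest falls of sgRNAs from day 0 to day 9 included those of PFDN2, MCM2, RIOK2 and AARS. PFDN2, a subunit of the prefoldin co-chaperone, fell by 4.10 on the log2 scale (SE 0.25). MCM2, part of the replicative DNA helicase, fell by 4.00 (SE 0.28). RIOK2, an atypical kinase of late 40S subunit maturation, fell by 3.83 (SE 0.16), and AARS, the cytosolic alanyl-tRNA synthetase, fell by 3.74 (SE 0.32). All 5 sgRNAs of each of these genes went down, although those of PFDN2 also lie within 1 kb of the sgRNAs of NIT1. SPI1, which encodes the myeloid transcription factor PU.1, had the largest rise, 0.74 (SE 0.08), with 5 of 5 sgRNAs up. NCOA6, a nuclear receptor coactivator, rose by 0.55 (SE 0.105), and GPS2, a subunit of the NCoR corepressor complex, rose by 0.53 (SE 0.10). Among 18905 genes, edgeR's quasi-likelihood test called 1806 at an adjusted p of 0.05, 163 higher and 1643 lower. Scaled to the control sgRNAs, 85 were higher and 1854 lower. The number of higher genes was 46 and 55 without wild-type day 0 replicates 1 and 2, 338 and 282 without wild-type day 9 replicates 1 and 2, and 101 and 100 without mutant day 0 replicates 1 and 2. Of the lower ones, 593 had fallen by more than 1 on the log2 scale, while no rise was that large. DESeq2 called 2763 genes, 701 higher and 2062 lower. GPS2 did not pass with fry over its sgRNAs (adjusted p = 0.107) or with a Mann-Whitney test against control sgRNAs (adjusted p = 0.346).

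Genes of ribosome production made up large groups among those that fell in wild-type cells. Of 47 genes for 60S ribosomal proteins, 32 fell (38 when adjusted over the list alone), with a median log2 change of -0.69, and RPL15, whose sgRNAs also lie near those of NKIRAS1, reached -3.40 (SE 0.32). Of 32 genes for 40S ribosomal proteins, 23 fell (25 over the list alone), with a median of -0.93, RPS13 at -2.55 (SE 0.24) among them. Of 54 nuclear 60S assembly factors, 44 fell (47 over the list alone; median -0.78), such as the helicase DDX56 at -2.31 (SE 0.13) and the GTPase GNL2 at -2.34 (SE 0.17). Of 55 factors of 40S assembly, 45 fell (51 over the list alone; median -0.86), BMS1 at -3.38 (SE 0.18) among them. Of 20 genes of RNA polymerase I and rDNA transcription, 12 fell (16 over the list alone; median -0.49). Of 18 genes in the list of cytoplasmic 60S maturation factors, 9 fell, also over the list alone, with a median of -0.34. They included EFTUD1, the GTPase that works with SBDS to release eIF6, at -0.94 (SE 0.09). This list overlaps that of the nuclear 60S assembly factors, so they are not separate classes. Both hold EIF6, GTPBP4, MRTO4, RSL24D1, SPATA5 and SPATA5L1.

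The mitochondrial ribosome had 67 of 75 genes lower (70 over the list alone; median -1.13), with MRPS17 at -3.03 (SE 0.16) and MRPL22 at -2.69 (SE 0.15). Mitochondrial complex I had 29 of 47 lower (32; median -0.44), with NDUFA8, near the sgRNAs of MORN5, at -1.93 (SE 0.15). The spliceosome core had 28 of 36 lower (31; median -0.93), with SNRPD1 at -3.33 (SE 0.23). DNA replication had 28 of 45 lower (35, and 1 higher; median -0.92), and Mediator and SAGA had 27 of 38 lower and 1 higher (30 and 1; median -0.82), with MED30 at -3.55 (SE 0.21). The 26S proteasome had 21 of 38 lower (26, and 1 higher; median -0.55), the RNA exosome and its cofactors 14 of 22 (15; median -0.45), and the translation initiation and elongation factors 16 of 34 (23; median -0.45). Cytosolic aminoacyl-tRNA synthetases had 16 of 23 lower and 1 higher (17 and 1; median -0.48), and heat shock and cytosolic folding had 13 of 27 lower (16; median -0.37), with the chaperonin subunit CCT2 at -1.86 (SE 0.15). In each bracket, the first count is the one adjusted over the list alone.

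Smaller shares fell in the remaining lists. Among K562 lineage and oncogene dependencies, 10 of 24 fell (10, and 1 higher, over the list alone; median -0.19). They included the erythroid transcription factor GATA1 at -3.09 (SE 0.20) and BCR, a partner in the BCR-ABL1 fusion of these cells, at -1.89 (SE 0.16). The integrated stress response had 7 of 21 lower (9 over the list alone; median -0.11), with EIF2B5 at -2.06 (SE 0.17). For ER membrane insertion and UFMylation it was 8 of 20 (9; median -0.19), with the translocon subunit SEC61A1 at -3.49 (SE 0.24). Ribosome-associated quality control and ribosome rescue had 10 of 37 lower and 1 higher (11 and 3; median -0.02), and ABCE1, the ribosome recycling factor, was at -2.47 (SE 0.19), with sgRNAs shared with ANAPC10. Cullin-RING and ubiquitin machinery had 9 of 29 lower (9, and 1 higher; median -0.14), mTORC1 activation 8 of 25 (8; median -0.13), nonsense-mediated decay 4 of 15 (5, and 1 higher; median -0.21), and the 5S RNP and p53 pathway 4 of 11 (4; median -0.06). Autophagy had 2 of 21 lower (2; median -0.02), growth restraint genes 1 of 27 (1; median 0.01), and mTORC1 restraint 0 of 18 (0; median -0.01), where edgeR gave no gene with an adjusted p under 0.05. Of 365 olfactory receptors, taken as genes not expressed here, 2 rose and 3 fell (0 and 0 over the list alone), with a median of 0.06.

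Against all other genes, 25 of the 28 lists shifted in wild-type cells by limma's camera with a preset correlation of 0.01, 24 of them down and the olfactory receptors up. Autophagy (adjusted p = 0.967), growth restraint genes (adjusted p = 0.70) and mTORC1 restraint (adjusted p = 0.358) did not. The olfactory receptors had been chosen as a list in which no change is expected. Camera called them (adjusted p = 0.00301) at a median of 0.06, where the control sgRNAs had 0.04. It therefore also calls offsets this small, and a list call alone does not show a growth effect. With an estimated correlation 20 lists passed in camera. The 5 that did not were ribosome-associated quality control (adjusted p = 0.071), the 5S RNP and p53 pathway (adjusted p = 0.198), cullin-RING and ubiquitin machinery (adjusted p = 0.0607), nonsense-mediated decay (adjusted p = 0.0875) and mTORC1 activation (adjusted p = 0.0516).

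**Figure D1:**
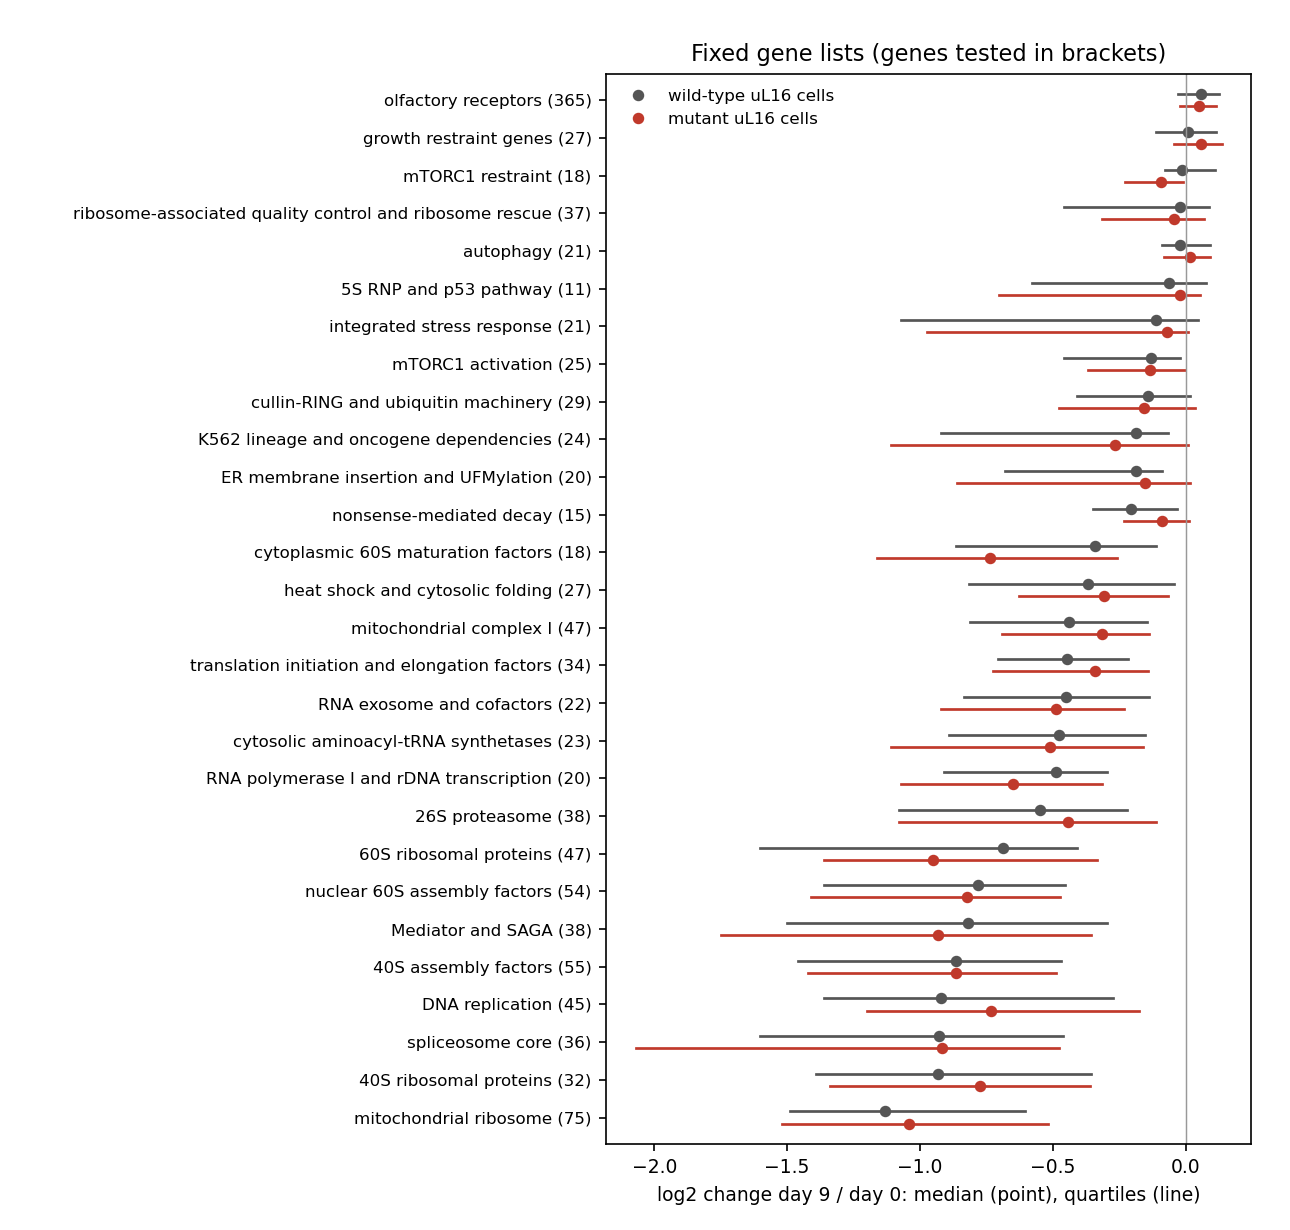
Median (point) and quartiles (line) of the log2 change from day 0 to day 9 over the genes of each fixed list, in wild-type (grey) and mutant (red) uL16 cells, with the number of genes tested in brackets. The mitochondrial ribosome has the lowest median in both lines (-1.13 and -1.04), and the cytoplasmic 60S maturation factors have medians of -0.34 in wild-type and -0.74 in mutant cells. Gene by gene, the median difference of the latter list between the lines was -0.13.

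In cells expressing mutant uL16, ZNF574, the zinc finger protein named in the title of the series, fell by 2.40 (SE 0.15), with 5 of 5 sgRNAs down. RPL10 itself fell by 1.27 (SE 0.16), with 4 of 4 sgRNAs down. The 10 largest falls included NOP2, an rRNA methyltransferase of 60S assembly, at -4.65 (SE 0.51), SEC61A1 at -4.45 (SE 0.25), WDR5, a subunit of histone methyltransferase complexes, at -4.42 (SE 0.40), and CHAF1B, a subunit of chromatin assembly factor 1, at -4.16 (SE 0.32). SPI1 rose by 0.78 (SE 0.08), NCOA6 by 0.78 (SE 0.10) and ARRDC3, an arrestin-domain protein, by 0.66 (SE 0.08), each with 5 of 5 sgRNAs up. edgeR called 1750 of 18905 genes at an adjusted p of 0.05, 137 higher and 1613 lower, of which 597 fell by more than 1 on the log2 scale. Scaled to the control sgRNAs, 67 were higher and 1775 lower. The number of higher genes was 80 and 83 without wild-type day 0 replicates 1 and 2, 237 and 236 without wild-type day 9 replicates 1 and 2, and 31 and 32 without mutant day 0 replicates 1 and 2. DESeq2 called 2395, 439 higher and 1956 lower.

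The cytoplasmic 60S maturation factors had 12 of 18 genes lower in mutant cells (13 over the list alone; median -0.74). Among them, EFTUD1 was at -1.16 (SE 0.09), LSG1, the GTPase that releases NMD3, at -1.57 (SE 0.15), NMD3, the export adaptor of the 60S subunit, at -1.13 (SE 0.13), ZNF622, a 60S-bound maturation factor, at -1.17 (SE 0.11), and DNAJC21, a J-domain protein, at -0.66 (SE 0.11). The 60S ribosomal proteins had 32 of 47 lower (37; median -0.95), with RPL34 at -2.85 (SE 0.24), and the 40S ribosomal proteins 23 of 32 (25; median -0.77). Nuclear 60S assembly factors had 42 of 54 lower (47; median -0.82), with DDX56 at -2.51 (SE 0.13). Factors of 40S assembly had 43 of 55 (48; median -0.86), with RIOK2 at -3.54 (SE 0.15). RNA polymerase I and rDNA transcription had 15 of 20 (15; median -0.65). Ribosome-associated quality control and ribosome rescue had 8 of 37 lower (8; median -0.04), with GCN1L1, a sensor of collided ribosomes, at -1.22 (SE 0.12). The mitochondrial ribosome had 68 of 75 lower (70; median -1.04), mitochondrial complex I 28 of 47 (31; median -0.32), the spliceosome core 26 of 36 (30; median -0.92), and DNA replication 30 of 45 (31, and 1 higher; median -0.73).

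For Mediator and SAGA it was 29 of 38 lower and 1 higher (31 and 2 over the list alone; median -0.93), for the 26S proteasome 19 of 38 (24; median -0.44), with PSMD4 at -2.85 (SE 0.20), and for the RNA exosome 13 of 22 (16, and 1 higher; median -0.49). Translation initiation and elongation factors had 15 of 34 lower and 1 higher (21 and 1; median -0.34), and aminoacyl-tRNA synthetases 15 of 23 (16, and 1 higher; median -0.51). Heat shock and cytosolic folding had 14 of 27 lower (16; median -0.31), K562 lineage and oncogene dependencies 11 of 24 (12; median -0.26), with GATA1 at -2.66 (SE 0.19), and ER membrane insertion and UFMylation 9 of 20 (9; median -0.15), with DDRGK1, part of the UFM1 ligase complex, at -1.26 (SE 0.11). The integrated stress response had 7 of 21 lower (7; median -0.07), cullin-RING and ubiquitin machinery 10 of 29 (11, and 1 higher; median -0.16), mTORC1 activation 7 of 25 (11; median -0.13), and the 5S RNP and p53 pathway 4 of 11 (4; median -0.02). Nonsense-mediated decay had 1 of 15 lower and 1 higher (2 and 1; median -0.09), autophagy 1 of 21 lower (1; median 0.02), and growth restraint genes 1 of 27 lower and 1 higher (1 and 1; median 0.06). Olfactory receptors had 1 of 365 lower and 2 higher (0 and 0; median 0.05). The mTORC1 restraint genes had 1 of 18 lower (0; median -0.09). That gene was LARP1, at -0.35 (SE 0.11). Without its most abundant sgRNA LARP1 had a log2 change of 0.12, and its call was also lost without either replicate of wild-type day 0 and mutant day 0, and without either mutant day 9 replicate (edgeR, adjusted p from 0.054 to 0.271).

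By camera with the preset correlation, 24 of the 28 lists shifted in mutant cells, 23 down and the olfactory receptors up. Nonsense-mediated decay (adjusted p = 0.296), autophagy (adjusted p = 0.90), mTORC1 restraint (adjusted p = 0.573) and growth restraint genes (adjusted p = 0.297) did not. The offset of the olfactory receptors was again small, a median of 0.05, where the control sgRNAs had 0.03. With an estimated correlation, camera's call was lost for the 5S RNP and p53 pathway (adjusted p = 0.14).

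The growth effects of the 2 lines went together, more closely by size than by rank. Across 18905 genes, which are not independent replicates, the log2 changes in wild-type and mutant cells had a Pearson correlation of 0.899 and a Spearman correlation of 0.435. The slope of mutant on wild-type changes was 1.02 by total least squares, which treats both lines alike and is not an ordinary regression. The changes of the 2 lines share no library. Single-library pairings gave correlations from 0.811 to 0.84. Of the genes called by edgeR, 1323 fell in both lines, where independent lists would share 140, and 27 rose in both, where independent lists would share 1.18. None of the 18905 genes passed in opposite directions, at an adjusted p of 0.05 in each line. Another 320 genes passed as lower in wild-type cells alone and 290 in mutant cells alone, but the difference itself passed for 3 genes.

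Which knockdowns slowed growth more in mutant than in wild-type cells was the question of the series. ZNF574 differed most: its log2 change was lower in mutant cells by a difference of -2.03 (SE 0.20), which is 4.08-fold, with 5 of 5 sgRNAs in that direction. Its summed sgRNAs had 40.1 ± 0.158 CPM (counts scaled to library size; mean ± SD, n = 2) at day 0 and 31.1 ± 5.07 at day 9 in wild-type cells. In mutant cells they had 40.5 ± 0.783 at day 0 and 7.68 ± 0.097 at day 9. ZNF622, whose product binds late 60S particles, differed by -0.97 (SE 0.15), with 5 of 5 sgRNAs, from a change of -0.20 (SE 0.11) in wild-type to -1.17 (SE 0.11) in mutant cells. RPL10 differed by -1.17 (SE 0.22), with 4 of 4 sgRNAs, from -0.09 (SE 0.15) to -1.27 (SE 0.16).

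In edgeR's test of the difference, these were the 3 genes of 18905 past the threshold, with adjusted p = 2.56e-07 for ZNF574, 0.00382 for ZNF622 and 0.0376 for RPL10. At an unadjusted p under 0.05 there were 1054 genes, 512 higher and 542 lower, where chance gives 945, and DESeq2 called 47. This unadjusted count was 700 without wild-type day 0 replicate 2, 458 and 631 without mutant day 0 replicates 1 and 2, and 1796 and 1705 without wild-type day 9 replicates 1 and 2, so it does not stand reliably above chance. In wild-type cells alone the change was not past the threshold in edgeR for ZNF574 (-0.37, SE 0.14, adjusted p = 0.0955), ZNF622 (adjusted p = 0.331) or RPL10 (adjusted p = 0.814). Limma on the mean log2 CPM of the sgRNAs did call the wild-type change for ZNF574 (-0.61, adjusted p = 0.0217) and for RPL10 (-0.99, adjusted p = 0.00652). The number of genes called for the difference was 1 without wild-type day 0 replicate 1, 18 without wild-type day 9 replicate 1, 5 without mutant day 9 replicate 1 and 5 without mutant day 9 replicate 2.

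The call for RPL10 was the weakest of the 3, past the threshold in 13 of 24 settings, against 22 each for ZNF574 and ZNF622. In edgeR it stayed past the threshold without wild-type day 9 replicate 1 (adjusted p = 0.00217) and without mutant day 9 replicate 2 (adjusted p = 0.0431). It was lost without wild-type day 0 replicate 1 (adjusted p = 0.739) or 2 (0.488), wild-type day 9 replicate 2 (0.128), mutant day 0 replicate 1 (0.234) or 2 (0.275), and mutant day 9 replicate 1 (0.155). The RPL10 difference was -0.45 (edgeR, adjusted p = 0.937) without its most abundant sgRNA. RPL10 was also not past the threshold with limma on mean log2 CPM (adjusted p = 0.90), Mann-Whitney (adjusted p = 0.0623) or all promoters pooled (edgeR, adjusted p = 0.0574). The RPL10 change in wild-type cells was 0.09 without wild-type day 9 replicate 1. ZNF622 lost its call without wild-type day 0 replicate 1 (edgeR, adjusted p = 0.285), and ZNF574 kept it in 8 of 8 such fits. With fry over sgRNAs, none of the 3 passed (adjusted p = 0.208 for ZNF574, 0.631 for ZNF622 and 0.667 for RPL10), a test that called 4 of 50 simulated genes with a difference of 2. When the sgRNAs of a separate second promoter were pooled in, ZNF574 differed by -0.29 (edgeR, adjusted p = 0.896), since that second set by itself differed by 0.19 (SE 0.13). Within 10 kb of the sgRNAs of ZNF574 and of ZNF622 lay 0 sets for other genes, and for RPL10 there was 1, the primary set of DNASE1L1 at 9.92 kb, which differed by 0.65 (SE 0.37).

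**Figure D2:**
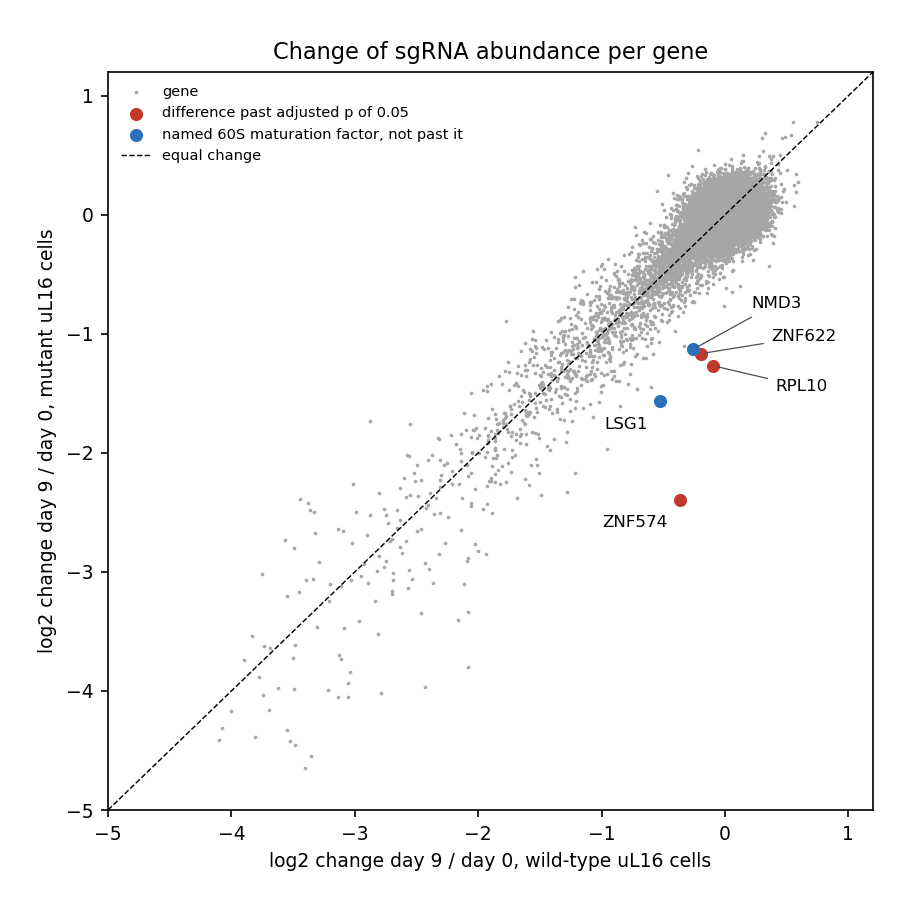
Log2 change from day 0 to day 9 of each of 18905 genes in wild-type (x axis) and mutant (y axis) uL16 cells, fitted from 2 libraries per group, with the dashed line at equal change. The 3 genes in red passed the threshold for the difference, with ZNF574 farthest below the line at -0.37 and -2.40, and the 2 genes in blue, LSG1 and NMD3, did not.

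**Figure D3:**
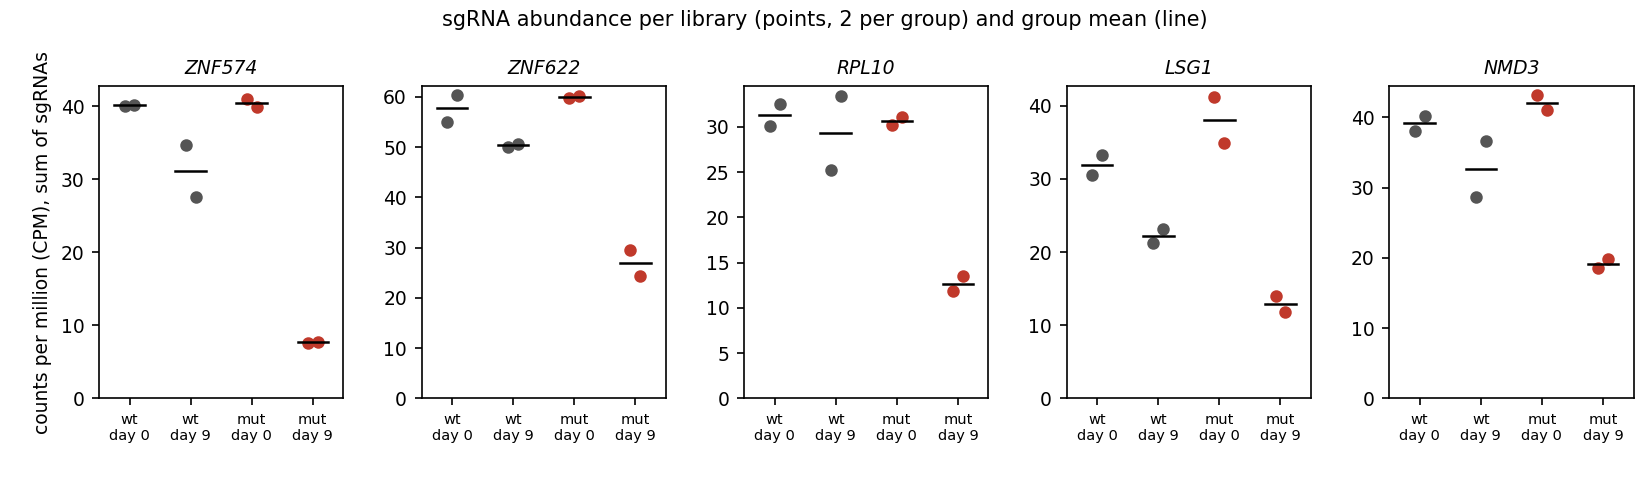
Summed sgRNA abundance in CPM of 5 genes in each library, with points for the 2 replicates and a line for their mean, in wild-type (grey, wt) and mutant (red, mut) cells at day 0 and day 9. Means for ZNF574 went from 40.1 to 31.1 in wild-type and from 40.5 to 7.68 in mutant cells.

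As a list, the cytoplasmic 60S maturation factors passed for the difference in camera with the preset correlation (adjusted p = 4.45e-06) but not with an estimated correlation (adjusted p = 0.133). That estimate was -0.0229, below the preset 0.01, so the call was not lost through a higher correlation between its genes. Of 18 genes, 1 (ZNF622) passed over all genes and 4 passed over the list alone, with a median difference of -0.13, and 13 of 18 had a negative value. LSG1 had a difference of -1.04 (SE 0.21, edgeR adjusted p = 0.0754), NMD3 of -0.87 (SE 0.19, adjusted p = 0.121) and DNAJC21 of -0.51 (SE 0.15, adjusted p = 0.725), none past the threshold over all genes. LSG1 passed in 5 of 24 settings and NMD3 in 3 of 24. With a replicate block within genotype both LSG1 (edgeR, adjusted p = 0.0164) and NMD3 (0.024) passed, as they did with DESeq2 (adjusted p = 0.000125 and 0.000714), and LSG1 passed with limma-voom per day (adjusted p = 0.0447). LSG1 also passed without wild-type day 9 replicate 1 (edgeR, adjusted p = 0.02) and without mutant day 9 replicate 1 (0.0456), and NMD3 without wild-type day 9 replicate 1 (0.00608). No other list of the 28 was called by camera at the preset correlation, and with an estimated correlation camera called 0 lists. Fry gave this list an adjusted p of 0.0485. Camera called 3 lists without wild-type day 9 replicate 2, and 2 lists each without mutant day 0 replicate 1 and without mutant day 9 replicate 1.

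**Figure D4:**
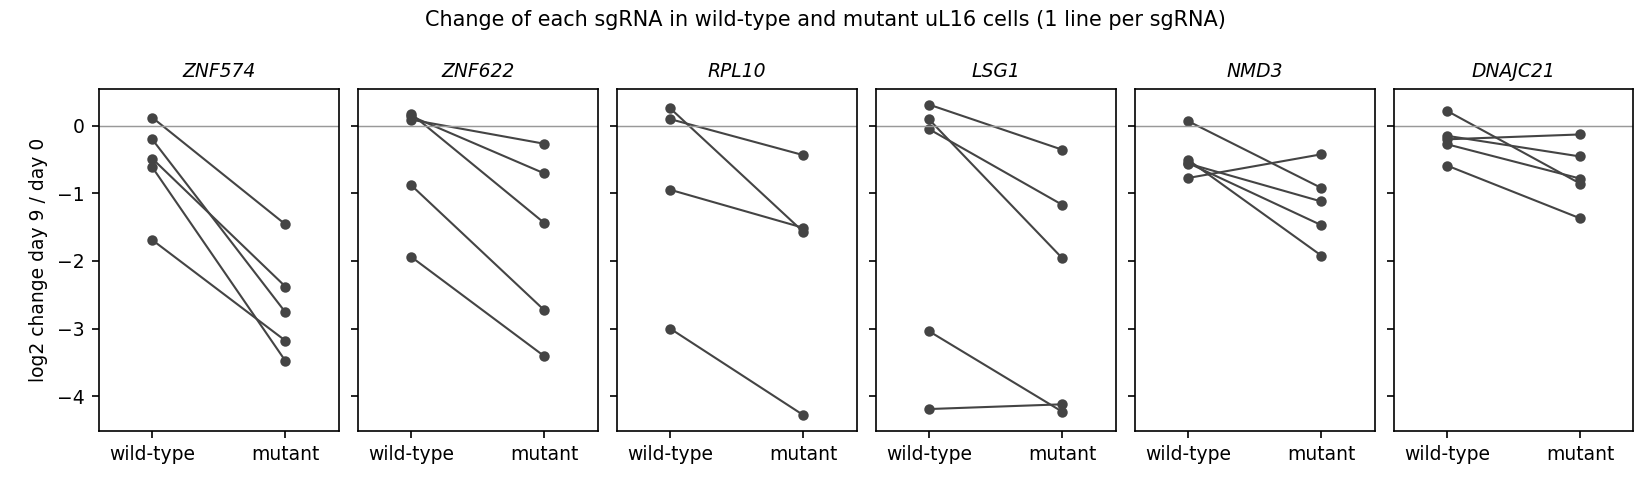
Log2 change from day 0 to day 9 of each sgRNA of 6 genes (1 line per sgRNA) in wild-type and mutant uL16 cells. All 5 lines of ZNF574, all 5 of ZNF622 and all 4 of RPL10 go down from wild-type to mutant cells, and 4 of 5 do for LSG1, NMD3 and DNAJC21.

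No other list passed in the difference. The 60S ribosomal proteins had a median difference of -0.04 and 1 gene lower, RPL10 (camera, adjusted p = 0.505). The values for ribosome-associated quality control were a median of 0.00 and 0 genes over all genes, with 2 lower over the list alone (camera, adjusted p = 0.505). In that list NEMF, which tags stalled chains on 60S complexes for degradation, had a difference of -0.84 (SE 0.21) with 5 of 5 sgRNAs down, not past the threshold (edgeR, adjusted p = 0.488). NEMF passed in 4 of 24 settings: without wild-type day 9 replicate 1 (edgeR, adjusted p = 0.0352), without mutant day 9 replicate 1 (0.0456), with Mann-Whitney (0.00613) and with limma-voom per day (0.025). Over the list alone, 1 gene was lower in the spliceosome core and 1 in DNA replication, 1 was higher in 40S assembly, and Mediator and SAGA had 1 of each. Single sgRNAs gave less than gene sums: edgeR called 0 of 95887 sgRNAs for the difference, with 4892 at an unadjusted p under 0.05, and DESeq2 called 116. Without 1 library this count was at most 3 (without wild-type day 9 replicate 2) and was 1 without wild-type day 9 replicate 1 and without mutant day 9 replicate 1. In simulated data the same test called 196 of 251 sgRNAs with a difference of 2 and 50 of 255 with a difference of 1.

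At day 9, mutant cells held less of ZNF574 than wild-type cells (log2 difference -2.02, SE 0.15) and less of RPL10 (-1.20, SE 0.16). MED11, a Mediator head subunit, was lower (-0.92, SE 0.20), as were SNRPE, a core protein of the spliceosomal snRNPs (-1.13, SE 0.24), and NUPL1, a nucleoporin with 3 kept sgRNAs (-1.50, SE 0.33). MED12, of the Mediator kinase module, was higher (0.96, SE 0.18), and so were BMS1 (0.92, SE 0.18), the elongin gene TCEB3 (0.58, SE 0.10) and NABP2, a single-stranded DNA binding protein (0.58, SE 0.11). Of the 18 cytoplasmic 60S maturation factors 4 were lower, also over the list alone: ZNF622 (-0.91, SE 0.11), LSG1 (-0.79, SE 0.15), NMD3 (-0.76, SE 0.13) and DNAJC21 (-0.52, SE 0.11). edgeR called 42 genes at an adjusted p of 0.05, 15 higher and 27 lower, and DESeq2 683. The 42 include the 3 genes of the difference, a test that uses the same day 9 libraries. Of the 42, 6 share sgRNAs with another gene, and DPY30 and MEMO1 among them have identical values. By camera, 2 lists were lower, the cytoplasmic 60S maturation factors (adjusted p = 8.95e-06) and mTORC1 restraint (adjusted p = 0.0109), and both were lost with an estimated correlation (adjusted p = 0.146 and 0.309). These estimates were -0.0215 and -0.0413, also below the preset value. Fry called both lists (adjusted p = 0.0131 each) and the nuclear 60S assembly factors (adjusted p = 0.0454).

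These day 9 counts changed with the libraries in the fit, a choice that alters the spread and its degrees of freedom together. With the spread shared by all 8 libraries, 50 of 378 control sets had an unadjusted p under 0.05 at day 9, where chance gives 19, and 1 passed the threshold. In a separate fit of the day 9 libraries alone, 8 genes passed in edgeR. The count was 20 without either wild-type day 0 replicate, 24 without either mutant day 0 replicate, 130 without wild-type day 9 replicate 1 and 124 without wild-type day 9 replicate 2. MED11, SNRPE, NUPL1, MED12, BMS1 and NABP2 did not pass in edgeR with the day 9 libraries alone (adjusted p from 0.0578 to 0.519). At least 1 fit without a library also ended each of these calls: MED12 without mutant day 9 replicate 1 (edgeR, adjusted p = 0.0709), NABP2 without wild-type day 9 replicate 1 (0.0624) or mutant day 9 replicate 2 (0.08), and BMS1 without wild-type day 0 replicate 1 (0.0631) or 2 (0.0568), wild-type day 9 replicate 1 (0.0587) or mutant day 9 replicate 1 (0.0709). NUPL1 was lost in every such fit except those without wild-type day 9 replicate 1 and mutant day 9 replicate 1 (0.103 to 0.256). MED11 and SNRPE were lost in edgeR without any 1 of the 4 day 0 libraries or mutant day 9 replicate 1 (adjusted p from 0.0846 to 0.147).

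At day 0, before the growth period, ZNF574 differed between mutant and wild-type cells by a log2 value of 0.01 (SE 0.13) and RPL10 by -0.03 (SE 0.15). edgeR called 0 of 18905 genes at day 0, with 250 at an unadjusted p under 0.05 where chance gives 945, and DESeq2 called 0, with 649 at an unadjusted p under 0.05. The 250 rests on a spread shared with the more variable day 9 libraries: with the day 0 libraries alone edgeR gave 1024 and limma-voom per day 1070, both with 0 genes called. Without mutant day 0 replicate 1 it was 67, and without either wild-type day 9 replicate 448.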

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

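The test of whether the genes called at day 9 already differed at day 0 was written before its result was seen, and the slope, the tests without 1 sgRNA, the comparison of RPL10 with other 60S ribosomal proteins and the control-set test were chosen only after it.

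A difference between the lines, tested directly, picked out ZNF574 (-2.03), ZNF622 (-0.97) and RPL10 (-1.17). If all growth effects were larger in mutant cells, through more doublings or stronger knockdown, the slope of mutant on wild-type changes would be far above 1. By total least squares it was 1.02 (0.966 to 1.07 without 1 library). An off-target effect of a single sgRNA is argued against for ZNF574, whose difference without its most negative sgRNA was -1.91 (SE 0.22), and for ZNF622, where it was -0.92 (SE 0.16). For RPL10 it was -0.45 (SE 0.34), so an off-target sgRNA cannot be told apart from an effect of RPL10. A hypothesis left for ZNF574 and ZNF622 is that their loss slows growth more when uL16 is mutant, which may also depend on differences between the 2 cell lines other than uL16 that these libraries do not separate.

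RPL10 passed the threshold in mutant but not in wild-type cells. A hypothesis is that the introduced wild-type gene is not reached by sgRNAs against the RPL10 promoter and stands in for it. With summed counts, 43 of the 46 other 60S ribosomal proteins (93.5%) had a more negative change than RPL10 in wild-type cells and 14 of 46 (30.4%) in mutant cells, but with the sgRNAs averaged it was 34 of 46 (73.9%) and 19 of 46 (41.3%). The averaged RPL10 change in wild-type cells was past the threshold (-0.99, limma, adjusted p = 0.00652), and 1 of its sgRNAs fell by 3.00 there, so this hypothesis cannot be told apart from no replacement.

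At day 9, 42 genes differed between the lines, against 3 in the difference of the growth effect. In the difference, which uses the same day 9 libraries, all 42 had the same sign and 41 an unadjusted p under 0.05 (edgeR). The median SE over genes was 0.107 at day 9 and 0.151 in the difference. That the 42 genes as a set already differed at day 0 is argued against by their median day 0 difference in the direction of day 9, -0.00569 (95% bootstrap interval -0.0248 to 0.0194, 10000 resamples), where the median size at day 9 was 0.67. At day 0, 20 of the 42 had the sign of day 9. The median does not speak for each gene: TMEM132B was at -0.59 at day 9 but -0.32 in the difference, and IWS1 at -0.79 and -0.53. The interval resamples genes measured in the same libraries, 6 of which share sgRNAs with another gene, so it leaves out the spread between libraries. A spread shared with the less variable day 0 libraries may be too small at day 9: 50 of 378 control sets had an unadjusted p under 0.05 there, where chance gives 19 (exact binomial p = 5.46e-10). With the day 9 libraries alone 8 genes passed.

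Signals in sgRNAs that the main tests left out were those of a separate second promoter. Of their 1395 sets, 17 (1.22%) passed the threshold in wild-type and 12 (0.86%) in mutant cells (edgeR, adjusted over these sets). The primary sets of the same genes passed more often, 114 (8.17%) in each line. Second-promoter sets passed where the primary set of the gene did not for 14 genes in wild-type and 10 in mutant cells. This held in both lines for 8 sets, all of them lower. Ranked by the changes of both lines added together, the largest falls among these 8 were those of 6 genes. Their values in wild-type cells were CENPA (-3.85), CBFA2T3 (-2.29), RCC1 (-1.38), OAZ3 (-0.763), DNASE1L1 (-0.532) and HR (-0.464). In wild-type cells the primary sets of the same genes had log2 changes of 0.05, -0.15, -0.20, 0.04, -0.30 and 0.11. Whether these second-promoter sgRNAs lie near the promoter of another gene was not tested, so a fall may belong to a neighbour. In the difference between lines, edgeR called 0 second-promoter sets, with 63 at an unadjusted p under 0.05.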

How the results depend on the processing

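Of the alternatives, limma-voom with a weight per day, the robust fit and leaving out genes that share sgRNAs were chosen after seeing the data. Of the 59 genes named for the difference 3 were called, and of the 2 named at day 0 none was. In these contrasts, keeping the side of the threshold therefore mostly means that uncalled genes stayed uncalled. Named genes kept their direction and side of the threshold in 1169 of 1210 values for wild-type cells, 1144 of 1177 for mutant cells and 857 of 884 for the difference, and in 98 of 130 at day 9 and 25 of 26 at day 0. Without 1 library, which leaves a lone replicate assumed to vary like the other groups, it was 584 of 608, 568 of 592, 459 of 472, 51 of 80 and 14 of 16. Signs turned for PWP2 in the difference (0.68 to -0.24 with limma on mean log2 CPM and with Mann-Whitney, -0.027 without the most abundant sgRNA), TTF1 in the difference (-0.39 to 0.0676 and 0.0684 with the same limma and Mann-Whitney tests) and LARP1 in mutant cells (-0.35 to 0.12 without the most abundant sgRNA). They also turned for ZNF574 at day 0 (-0.0196 with all promoters pooled, and -0.00667 without mutant day 0 replicate 1 in a range to 0.0328), RPL10 at day 0 (-0.0848 to 0.028, positive without wild-type day 0 replicate 2) and RPL10 in wild-type cells (-0.312 to 0.0928, positive without wild-type day 9 replicate 1). Genes called in wild-type cells were 593 with a log2 change over 1 added, 2763 with DESeq2, 1176 with fry and 964 with Mann-Whitney. In mutant cells they were 597 with the added threshold and 1043 with Mann-Whitney. Of the genes called by DESeq2, 701 were higher and 2062 lower in wild-type and 439 and 1956 in mutant cells. For the difference, counts were 47 with DESeq2, 0 with fry (which called 0 of 50 simulated genes at 1 and 4 of 50 at 2), 6 with Mann-Whitney, 1 with all promoters pooled and 6 with limma-voom per day. At day 9 they were 683 with DESeq2, 19 with limma on mean log2 CPM, 0 with fry, 8 with only the libraries compared and 14 with limma-voom per day. Lists past the threshold in the difference fell to 0 with camera and an estimated correlation. DESeq2 called 116 sgRNAs for the difference. Pooling promoters adds second-promoter sgRNAs, and the added threshold is stricter by construction; for the other changes the cause was not tested. Without 1 library, counts ranged from 1298 to 1993 (wild-type), 1234 to 2029 (mutant), 1 to 18 (difference), 20 to 130 (day 9) and 0 to 0 (day 0), lists from 22 to 25, 23 to 24 and 1 to 3, single sgRNAs from 0 to 3, and the correlation of the lines from 0.863 to 0.894. In simulation, with equal changes over the sgRNAs of a gene, 38% of genes with a difference of 0.5 were called.

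With a replicate block the difference had 5 genes, and with a replicate block within genotype it had 9. Both counts include DPY30 and MEMO1, which share sgRNAs and have identical values. Deviations of same-numbered libraries correlated at -0.00727 to 0.0467 over genes, highest between days within a line (0.0233 in wild-type and 0.0467 in mutant cells). Such low values neither show nor exclude a weak pairing of the samples by replicate number. The gene counts of wild-type and of mutant cells moved by less than 1.5 times under either block. At day 9 and day 0 only the first block was fitted, with 39 and 0 genes.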

Other observations

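The genes in this part were chosen after their values were seen. In both lines, 27 genes rose, 26 of them in no fixed list. Next to SPI1, NCOA6 and GPS2 they held both subunits of the PAN deadenylase, which trims poly(A) tails: PAN2 rose by 0.39 (SE 0.07) in wild-type and 0.49 (SE 0.07) in mutant cells, and PAN3 by 0.32 (SE 0.10) and 0.40 (SE 0.10), with 5 of 5 sgRNAs up for each. Others among the 27 were MTF2, an accessory subunit of Polycomb repressive complex PRC2 (0.43, SE 0.09, and 0.43, SE 0.09), the arginine methyltransferase CARM1 (0.43, SE 0.09, and 0.38, SE 0.09), the acetyltransferase KAT7 (0.27, SE 0.08, and 0.49, SE 0.08) and ING1 (0.37, SE 0.11, and 0.44, SE 0.11). Among 378 sets of 5 control sgRNAs the highest changes were 0.496 in wild-type and 0.369 in mutant cells, so rises below these values lie within the range of the controls. Whether any class of genes is enriched among the 27 was not tested.

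Of 1323 genes that fell in both lines, 889 were in no fixed list. HSD17B10, a subunit of the mitochondrial tRNA-processing enzyme, was at -3.45 (SE 0.14) in wild-type and -3.17 (SE 0.14) in mutant cells. CAD, which starts pyrimidine synthesis, was at -3.30 (SE 0.23) and -3.46 (SE 0.22), and MTHFD1, of cytosolic folate metabolism, at -3.11 (SE 0.21) and -3.73 (SE 0.22). Genes of chromosome segregation included the kinetochore genes CENPI at -3.50 (SE 0.22) and -3.98 (SE 0.23) and DSN1 at -2.82 (SE 0.20) and -3.52 (SE 0.20), and AURKB at -2.77 (SE 0.24) and -2.96 (SE 0.24). CPSF1, of the mRNA cleavage and polyadenylation complex, was at -3.02 (SE 0.14) and -2.76 (SE 0.14). Enrichment of any class of genes among the 889 was not tested either.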
